A study of Locusta migratoria with 12 samples.

How the data were processed

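Transcript abundance was measured by RNA sequencing in 12 libraries of mixed fat body and ovary from adult female *Locusta migratoria*: 3 treatments (Sephadex beads, *M. luteus*, larvae of *B. lapidosa*) at 4 h and 6 d, with 2 libraries per group. A needle-stab group described in the labels has no samples in the series and was not analysed here. The labels give the Sephadex grade as a number that runs from 50 to 53 over the 4 Sephadex samples, and these were treated as 1 reagent.

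The deposited files hold expected counts from RSEM (Read_count, reads per assembled component, with decimals in 15.9% to 20.4% of components) and RPKM (reads scaled to transcript length and library size), as the authors computed them. RSEM is the only tool named in the submitters' notes. Its version, the assembler, the aligner and the annotation tools are not given in the sources used here. Only components of 0.3 RPKM or more are listed for a library. Unlisted components were set to 0, and the totals implied by RPKM show that unlisted reads make up at most 0.0394% of a library. Listed reads per library ran from 7991021 to 12981849. Of 54085 components in any library 19535 were listed in all 12, and 11971 had a name, taken from the deposited best hits.

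Expected counts were rounded and tested with the edgeR quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with TMM scaling, filterByExpr (19866 genes kept, 34219 dropped), a model of 6 group means over all 12 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. The common biological coefficient of variation was 0.267, the residual degrees of freedom 6 and the prior degrees of freedom 2.85. The SE of a log2 fold change was its absolute value over the square root of F. Values are TMM-scaled CPM with SD over n = 2. There were 11 comparisons: each parasite against Sephadex at each time, fly against bacterium at each time, 6 d against 4 h in each treatment, and 2 tests of a change of the effect between the times. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 served for loading and plots.

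The test and the lists were tested on simulated data with known changes. Each gene had its mean and spread as estimated over all 12 libraries, not those of a comparison. With the changes put into bacterium at 4 h, 13% of 2-fold and 58% of 4-fold changes passed (7 false among 78 calls). With them put into fly at 6 d, 14% and 55% passed (1 false among 70).

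The letters A and B were checked for pairing. Over the 15 pairs of groups, correlations of the differences between replicates ran from -0.1 to 0.15 with a median of 0.03, so no replicate block was fitted in the main test and the block was run as an alternative.

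There were 21 gene lists, matched on names: pattern recognition, Toll, IMD and JAK/STAT signalling, antimicrobial peptides and lysozymes, melanization and serine protease cascade, haemocyte markers, antioxidant and glutathione enzymes, heat shock proteins and chaperones, cytochrome P450 and other detoxification enzymes, yolk and storage proteins, lipid and sugar metabolism, juvenile hormone pathway, ecdysone pathway, insulin and TOR pathway, 2 ovary lists, cell cycle and DNA replication, ribosomal proteins, and markers of muscle, gut, cuticle and nerve. They were tested with camera on log2 CPM (prior count 2, preset correlation 0.01, an estimated correlation beside it), adjusted over the lists and the 9 comparisons of 2 groups. The lists, comparisons, tests and all recomputations not listed as added below were fixed before the data were examined. List medians were also computed with genes that were absent from one group held at the listing limit.

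Named genes were chosen by rule: among genes past the test, with both libraries of a group above both of the other, a mean of 5 CPM or more and an informative name, those with the largest changes in each direction; for each list, up to 4 members with the smallest p; and, as counts, every vitellogenin, vitellogenin receptor, lysozyme, defensin, peptidoglycan recognition protein and prophenoloxidase. Every gene of the largest-change part is named in the text, while of the list members only some are named, and these were picked after their values were seen. Followed genes are those whose calls were traced through every alternative. Genes with no listed reads in both libraries of a group are given by their CPM and not by a fitted fold. Diptericin comp48786_c0 and Defensin-1 are shown per library for their levels, which were seen first.

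Each result was recomputed with a replicate block, the DESeq2 Wald test (DESeq2 1.42.0), RLE size factors, no filter, a filter of 1 CPM in 4 libraries, a fit of only the libraries compared, an absolute log2 fold change of at least 1, and leaving out each library in turn, with the gene set of the main test and a lone sample assumed to vary like the other groups. For lists they were an estimated correlation, the replicate block, and lists without members on another list. Added after seeing the data were a term for the libraries under 1% of reads in comp60900_c0, unlisted components at the listing limit, lists with members checked by name (also with an estimated correlation), the camera test with that term and without each library in turn, a minimum of 5 reads for genes seen in the fly libraries alone, and 1 Sephadex library for each of the bacterium and fly comparisons. Shared calls were set against 100 simulations that drew the 6 libraries of a time from 1 mean per gene.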

Results

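RNA sequencing measured transcript abundance in pooled fat body and ovary of adult female migratory locusts (*Locusta migratoria*) that were treated on the first day after molting. The 12 libraries form 6 groups of 2, with the letters A and B as replicates. Females had received Sephadex beads (inert dextran particles that simulate a parasite, 100 µl of 50 mg/ml), a culture of the bacterium *M. luteus* (10 µl at an OD600 of 0.9), or larvae of the fly *B. lapidosa* placed in a wound, and were sampled 4 h or 6 d later. Between 7991021 and 12981849 reads were listed per library, over 36218 to 41275 assembled components, which are called genes here. Of 54085 genes in any library, 11971 (22.1%) had a name from a sequence match, and 19866 were tested. The labels do not say that replicates came from separate animals or pools and mention a parallel replication, so the p-values measure only the spread between these samples, which may be technical. Each group value below rests on n = 2, and errors of log2 fold changes are SE.

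Time after treatment was the main axis of the samples: the first principal component held 35.7% of the variance and the second 15.2%. Replicates correlated across genes at a Pearson r of 0.98 to 0.983 in Sephadex at both times and bacterium at 4 h, 0.972 in fly at 4 h, 0.963 in bacterium at 6 d and 0.954 in fly at 6 d, and genes are not independent replicates. Fly 6 d A and bacterium 6 d B lay away from their partners. One component, comp60900_c0, took 0.244% to 0.267% of the reads in the B libraries of Sephadex and bacterium at both times and 2.8% to 4.82% in the other 8 libraries, so this split is balanced within Sephadex and bacterium but every fly library is on the high side. A pair against a pair limits detection. On data simulated with the spread estimated over all 12 libraries, 13% of 2-fold and 58% of 4-fold changes put into bacterium at 4 h passed.

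**Figure D1:**
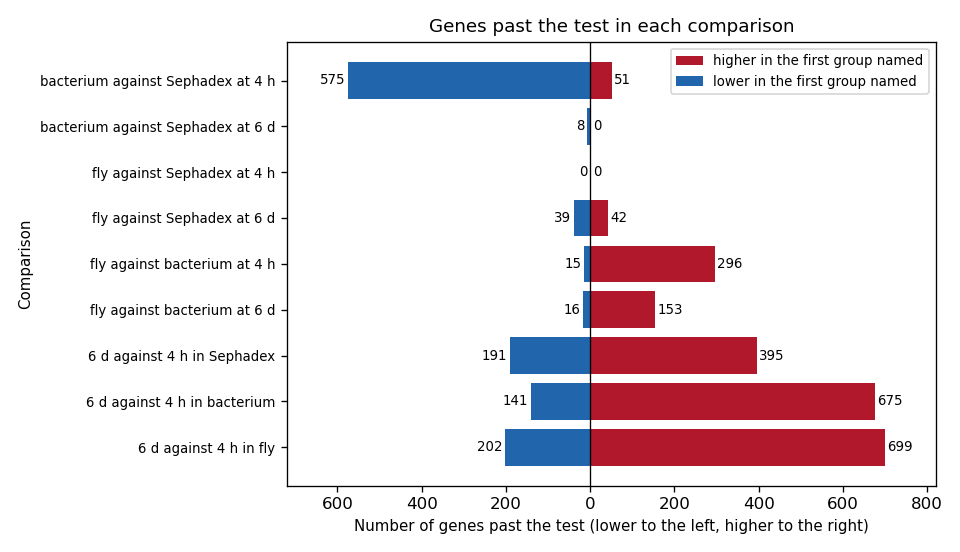
Number of genes past the edgeR test (adjusted p under 0.05) in the 9 comparisons of 2 groups, with genes lower in the first group named as bars to the left and higher genes as bars to the right. The bacterium libraries at 4 h had 575 lower and 51 higher genes than Sephadex, and no gene passed for the fly at 4 h.

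Bacterium against Sephadex at 4 h asks what an early bacterial infection changes beyond an inert foreign body. Of the genes that passed, most fell, among them 15 cuticle, 16 muscle and 21 detoxification genes. Of 27 cuticle genes, 15 fell and none rose (20 lower when adjusted over the list alone), with a median log2 fold change of -2.61. Endocuticle glycoprotein SgAbd-8 (comp55933_c0), a structural protein of the inner cuticle, changed by -5.76 ± 0.54, from 77.2 ± 13.2 to 1.42 ± 0.332 CPM (counts scaled to library size, SD, n = 2), and obstructor-A (comp50365_c0), a chitin-binding protein, by -3.6 ± 0.17 (adjusted p = 0.00011). Of 59 muscle markers, 16 fell (30 lower and 1 higher over the list alone, median -1.02), among them paramyosin (comp52724_c0, -1.71 ± 0.23), a thick filament protein, troponin T (comp47712_c0, -1.38 ± 0.19), which regulates contraction, and muscle LIM protein Mlp84B (comp54328_c0, -1.45 ± 0.18). Of 180 cytochrome P450 and other detoxification genes, 21 fell (51 lower and 2 higher over the list alone). Their median was -1.07, or -0.86 with genes absent from one group held at the listing limit. The list summed to 6190 and 6750 CPM in bacterium against 6890 and 7380 in Sephadex. Examples are P450 CYP4C62 (comp58468_c0, -3.27 ± 0.4) and UDP-glucuronosyltransferase 2B20 (comp58794_c1, -4.32 ± 0.84).

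Few fat body and hormone genes passed in the bacterium libraries at 4 h. Of 21 yolk and storage protein genes, 3 fell (6 lower over the list alone, median -0.79, or -0.7 with bounds), among them hexamerin-like protein 2 (comp59924_c0), an amino acid storage protein, at 35.6 ± 2.24 against 321 ± 70.4 CPM (log2 fold change -3.17 ± 0.6). None of the 5 vitellogenin (yolk protein precursor) genes or 8 vitellogenin receptor genes passed. On the juvenile hormone list 4 of 47 fell (5 lower over the list alone): 3 takeout genes, of a family of carriers of small lipids, and juvenile hormone esterase (comp57377_c0, -2.17 ± 0.48), which breaks the hormone down. Takeout (comp57634_c0) went from 212 ± 19 to 58.8 ± 3.72 CPM (adjusted p = 0.00065). Superoxide dismutase (comp52900_c0, -2.02 ± 0.45) fell and glutathione synthetase (comp54234_c0, 0.53 ± 0.11), which makes glutathione, rose, the only 2 of 68 antioxidant genes to pass.

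Among genes with an informative name, the largest rise in the bacterium libraries at 4 h was that of the probable G-protein coupled receptor No18 (comp48606_c0), at 29.9 ± 1.27 against 0.375 ± 0.531 CPM (6.28 ± 1.23, adjusted p = 0.048). The next were ankyrin repeat protein (comp60611_c0, 1.34 ± 0.2), the small GTPase Di-Ras2 (comp56832_c0, 1.2 ± 0.14), Mitotic-spindle organizing protein 1 (comp60452_c1, 1.18 ± 0.18), seipin (comp59466_c0, 0.88 ± 0.19, and comp59466_c1, 0.77 ± 0.1), a lipid droplet protein, sorting nexin-21 (comp59344_c1, 0.86 ± 0.16) and aminoacylase-1-like (comp55361_c0, 0.86 ± 0.17). Serpin peptidase inhibitor 5 (comp47702_c0) rose by 0.84 ± 0.18, Ras GTPase-activating protein 1 (comp52231_c0) by 0.82 ± 0.16, the DNA repair enzyme methylated-DNA-protein-cysteine methyltransferase (comp55050_c0) by 0.82 ± 0.17, DNA polymerase delta small subunit (comp42436_c0) by 0.78 ± 0.15 and dihydropyrimidinase-like (comp56862_c0) by 0.69 ± 0.15. A UFM1-specific peptidase domain protein (comp59534_c2, 0.67 ± 0.1), a Werner Syndrome-like exonuclease (comp54383_c0, 0.66 ± 0.13) and the ecdysone-response factor broad-complex Z2 (comp59123_c3, 0.64 ± 0.13) also rose. The largest falls besides SgAbd-8 and those given above were Lachesin (comp60792_c1), a cell surface protein with 8.51 and 7.4 CPM in Sephadex and no listed reads in bacterium, and a pacifastin-related peptide (comp53092_c0, -6.13 ± 0.96), of a family of protease inhibitors. SgAbd-2 (comp52240_c0) changed by -4.64 ± 0.66, P450 6k1-like (comp54677_c0) by -4.45 ± 0.95, a further P450 (comp52586_c0) by -4.37 ± 0.91, Tyrosine-protein kinase receptor Tie-1 (comp58172_c0) by -4.33 ± 0.73, trimethyllysine dioxygenase (comp50782_c0), of carnitine synthesis, by -4.2 ± 0.58 and P450 4c3 (comp54348_c0) by -3.98 ± 0.77. The Sephadex libraries disagreed on P450 6k1-like, at 12.3 and 104 CPM against 1.36 and 4.04 in bacterium.

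Among immune genes, few passed in the bacterium libraries at 4 h. Diptericins, antibacterial peptides, had 47.3 and 57.8 CPM (comp55410_c0) and 39.7 and 47.9 CPM (comp53811_c0) in the 2 bacterium libraries against 0.631 and 2.79, and 0.631 and 0.643, in Sephadex. These log2 differences of 4.94 ± 1.49 and 6.07 ± 1.9 did not pass with all 12 libraries (adjusted p = 0.12 and 0.13). They passed in fits without fly 6 d A (adjusted p = 0.007 and 0.00024), without fly 6 d B (0.0059 and 2.6e-05), with the 4 compared libraries (0.015 and 0.0037), with DESeq2 (0.01 and 0.0031) and with no filter (0.035 and 0.04). A c-3 lysozyme (comp59278_c0) had 17.4 and 67.8 CPM against 0 listed reads in both Sephadex libraries (adjusted p = 0.18). GNBP3 (comp53744_c0), a recognition protein for microbial glucans, stood at 63.4 ± 2.19 against 26.6 ± 1.65 CPM (adjusted p = 0.067). Of 16 antimicrobial peptide and lysozyme genes, only an I-type lysozyme (comp56111_c0, -2.58 ± 0.54) passed, and 3 were higher and 3 lower over the list alone. The list's median was -0.42 and its mean 1.07 (camera adjusted p = 0.97). On the melanization and serine protease list 1 of 55 rose and 7 fell, including 2 of 7 prophenoloxidases, precursors of the melanin-forming enzyme (comp50812_c0 at 1.68 and 0.751 and comp48961_c0 at 1.26 and 0.751 CPM in Sephadex, unlisted in bacterium). For comp50812_c0, of 2595 bases, the lower Sephadex value lies near the listing limit of 0.3 RPKM. Unlisted values were set to 0, so these 2 falls rest on low counts and their size is uncertain. Scavenger receptor class B member 1 (comp58791_c0, -3.4 ± 0.55) was 1 of the 2 of 36 pattern recognition genes that fell.

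**Figure D2:**
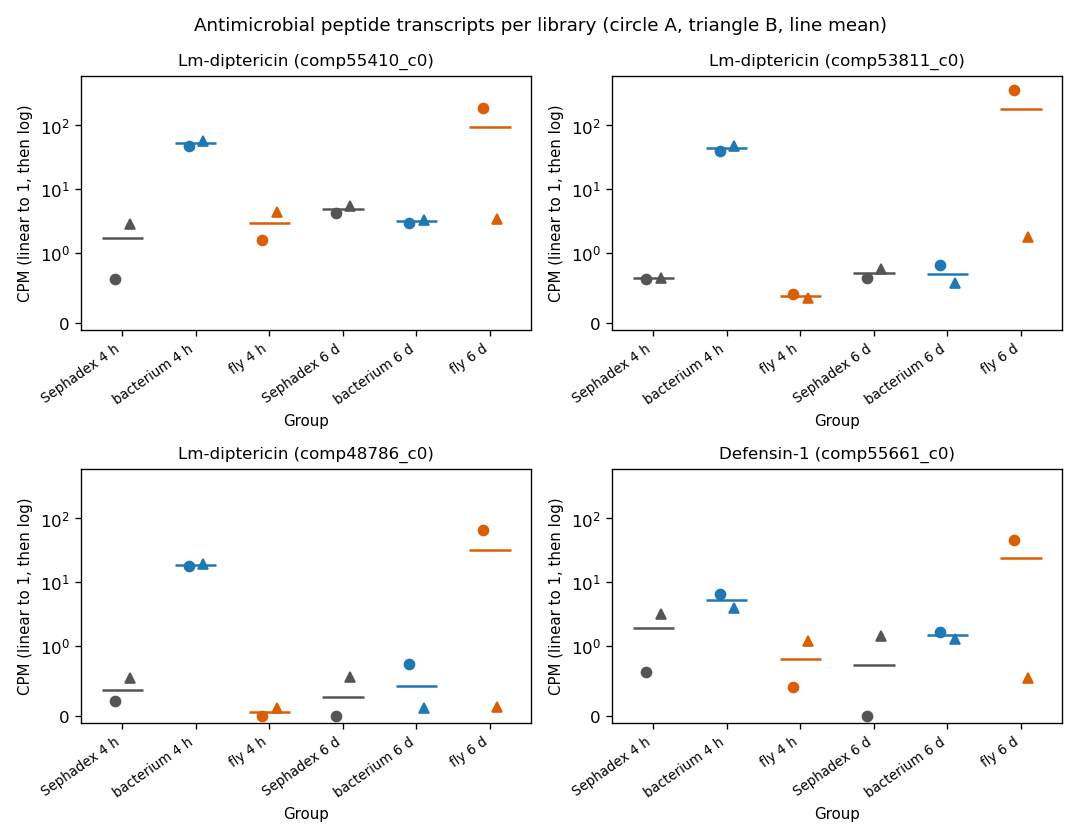
CPM of 3 diptericins and Defensin-1 in each library (circle A, triangle B, line the group mean; axis linear up to 1 and logarithmic above). The bacterium 4 h libraries held 47.3 and 57.8 CPM of comp55410_c0, and the highest value of each gene was in fly 6 d A.

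In this comparison 626 genes passed (51 higher, 575 lower; 4061 at an unadjusted p under 0.05). With camera, adjusted p was 1.5e-13 for cuticle, 7.7e-07 for muscle, 1.5e-05 for detoxification, 0.012 for yolk and storage, 0.047 for ribosomal proteins (1 of 154 fell, median -0.18) and 0.0066 for heat shock proteins (0 of 64 passed, median 0.09), all lower except the last. With an estimated correlation, adjusted p = 0.34, 0.46, 0.46, 0.57, 0.86 and 0.37 in this order, so no call held. The ribosomal call also ended with the term for comp60900_c0 (adjusted p = 0.072). It ended without Sephadex 4 h A (0.05) and B (0.19), Sephadex 6 d A (0.1) and B (0.095), bacterium 4 h A (0.39), bacterium 6 d A (0.078) and B (0.061), and fly 4 h A (0.06) and B (0.056). The storage call ended without bacterium 4 h B (0.083). DESeq2 called 1323 genes and a fit of the 4 compared libraries 1252. Leaving out 1 library gave 39 calls without bacterium 4 h A, 279 without bacterium 4 h B, 116 and 134 without Sephadex 4 h A and B, and 368 and 372 without Sephadex 6 d A and B, and of 44 followed genes that passed, 38 lost their call without bacterium 4 h A.

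Bacterium against Sephadex at 6 d asks what remained after the acute phase. Only 8 genes passed, and none of 21 storage or 154 ribosomal protein genes was among them. The storage list had a median log2 difference of -1.65 (-1.52 with bounds), with 8 genes lower over the list alone (camera adjusted p = 5.5e-09, and adjusted p = 0.37 with an estimated correlation). Hexamerin-like protein 2 (comp59924_c0) had 3730 ± 1250 against 38000 ± 15700 CPM (-3.35 ± 0.6, adjusted p = 0.13), juvenile hormone binding protein (comp60465_c0) 598 ± 156 against 3140 ± 1360 CPM (adjusted p = 0.18) and transferrin (comp57032_c0), an iron carrier, 5470 ± 2610 against 16100 ± 1130 CPM (adjusted p = 0.23). On the ribosomal list 75 genes were lower and 2 higher over the list alone (median -0.4, camera adjusted p = 5.7e-12, and adjusted p = 0.49 with an estimated correlation), such as L23A (comp51892_c0) at 422 ± 32.7 against 670 ± 13 CPM. The only named gene that fell was venom carboxylesterase-6-like (comp59057_c0, -1.68 ± 0.2, adjusted p = 0.042). The prophenoloxidase comp50812_c0 had 2.8 ± 0.221 against 24.4 ± 1.65 CPM (adjusted p = 0.069).

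At 6 d 8 genes passed for the bacterium, all lower (2269 at an unadjusted p under 0.05). Beside the storage and ribosomal lists, camera gave adjusted p = 0.0028 for detoxification (1 of 180 fell, median -0.32), 0.0029 for cuticle (median -0.46), 0.035 for melanization (median -0.1), all lower, and 0.022 for heat shock proteins (median 0.09, higher). With an estimated correlation adjusted p = 0.57, 0.5, 0.49 and 0.41, so none held. The melanization call ended without bacterium 6 d B, which stands apart (adjusted p = 0.48), Sephadex 6 d B (0.19), and fly 4 h A (0.06) and B (0.056). The heat shock call ended without fly 6 d A (0.057), Sephadex 6 d A (0.18) and bacterium 6 d A (0.23). The count was 415 with DESeq2, 106 with no filter, 46 with unlisted genes at the listing limit (an alternative added after seeing the data) and 0 with the 4 compared libraries. Leaving out 1 library gave 3 calls without either Sephadex 4 h library, 4 and 1 without Sephadex 6 d A and B, 4 without any 1 of the bacterium 4 h or fly 4 h libraries, 13 without bacterium 6 d A, 10 without bacterium 6 d B, and 76 and 73 without fly 6 d A and B. The venom carboxylesterase call ended with the replicate block (adjusted p = 0.071), with the comp60900_c0 term (0.081), with the 4 compared libraries (0.11) and without any 1 of the Sephadex or bacterium libraries.

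Fly against Sephadex at 4 h compares living larvae, placed in a wound, with an inert foreign body early on. No gene passed the edgeR test, and the smallest adjusted p was 0.18. Protein toll (comp60344_c0), a receptor of innate immunity and development, had 20.5 ± 1.94 against 6.68 ± 0.806 CPM (1.61 ± 0.41, adjusted p = 0.89). Thaumatin-like protein 1 (comp50965_c0), of a family with antifungal members, was at 7.05 CPM in fly A and 314 in fly B against 12.3 and 3.22 in Sephadex, and its difference of 4.36 was -0.14 without fly 4 h B. With all 12 libraries and every matched member, cuticle genes were the 1 list with a camera call, at a median of -0.63 over 27 genes, 0 of which passed and 1 of which was lower over the list alone (adjusted p = 2.9e-06, and adjusted p = 0.41 with an estimated correlation). The cell cycle list was called higher once its mobile-element names were left out, a check added after seeing the data (adjusted p = 0.01, and adjusted p = 0.75 with an estimated correlation). At an unadjusted p under 0.05 there were 828 of 19866 genes, less than the share of 0.05 that would be there with no change, and DESeq2 called 31. The count was 1 without fly 4 h A, 2 with no filter, 2 with the 4 compared libraries and 0 with the term for comp60900_c0.

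Fly against Sephadex at 6 d asks how an established infestation differs from the beads. Of 81 genes that passed 42 rose and 39 fell. The LPS-induced TNF-alpha factor homolog (comp51431_c0), of a family linked to inflammatory signalling, rose by 3.35 ± 0.3, from 24 ± 1.07 to 245 ± 115 CPM (adjusted p = 0.0045). Proclotting enzyme (comp49816_c0), a protease of haemolymph clotting, rose by 2.57 ± 0.4, protein toll (comp60344_c0) by 2.37 ± 0.38, to 161 ± 2.32 from 31.1 ± 0.967 CPM, and nitric oxide synthase (comp60618_c0), the source of nitric oxide, by 1.88 ± 0.23. TGF-beta-induced protein ig-h3 (comp56451_c0) rose by 2.82 ± 0.32, BRCA1-associated protein-like (comp57975_c0) by 2.63 ± 0.38, a plasma membrane protein (comp54797_c0) by 2.63 ± 0.43, collagen alpha-1(XV) (comp60634_c0) by 2.1 ± 0.28 and lysyl oxidase homolog 2 (comp59360_c0), a collagen cross-linker, by 1.98 ± 0.31. Aquaporin (comp50626_c0), a water channel, rose by 2.13 ± 0.21, Icarapin-like (comp53999_c0) by 2 ± 0.17, histidine decarboxylase (comp59546_c0), which makes histamine, by 3.08 ± 0.46, the sodium pump subunit beta-2 (comp50239_c0) by 2.35 ± 0.34 and LDL receptor-related protein 1 (comp59929_c0) by 1.86 ± 0.21.

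Among genes with an informative name, the largest fall of this comparison was that of D-arabinitol dehydrogenase 1 (comp56063_c0, -6.13 ± 0.86), an enzyme of sugar alcohol metabolism. Of 7 prophenoloxidases 2 were lower in fly than in Sephadex: comp50812_c0 was at 1.1 ± 0.0261 against 24.4 ± 1.65 CPM (-4.46 ± 0.45, adjusted p = 0.011) and comp56535_c0 at 1.43 ± 0.685 against 22.5 ± 0.307. Sephadex was the group in which comp56535_c0 rose most. This gene had no listed reads in any 4 h library. At 6 d it had 22.3 and 22.8 CPM in Sephadex, 1.98 and 1.14 in bacterium and 1.91 and 0.943 in fly. In Sephadex comp50812_c0 was also higher at 6 d than at 4 h. The melanization list had 1 of 55 higher and 2 lower (7 and 3 over the list alone, median 0.28, camera adjusted p = 0.15). Of 21 yolk and storage genes 2 fell (4 higher and 5 lower over the list alone): hexamerin-like protein 1 (comp59307_c1) had 64.7 ± 8.26 against 810 ± 33.5 CPM and arylphorin hexamerin-like protein 2 (comp58752_c0) 10.9 ± 0.779 against 127 ± 74.6. The storage list as a whole summed to 126000 and 58600 CPM in fly against 86800 and 60400 in Sephadex. Hexokinase-1-like (comp55062_c0), which starts glycolysis, changed by -1.74 ± 0.2, venom carboxylesterase-6-like (comp59057_c0) by -1.67 ± 0.2 and the circadian clock protein PERIOD (comp55272_c0) by -1.41 ± 0.17. A SEC14 phosphatidylinositol transfer protein (comp52651_c0, -2.04 ± 0.32), nuclear protein p8 (comp42017_c0, -1.78 ± 0.29) and lambda-crystallin homolog (comp42968_c0, -1.55 ± 0.23) fell as well. None of the 5 vitellogenins, 8 vitellogenin receptors, 8 lysozymes or 12 peptidoglycan recognition proteins passed.

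On the gut and antimicrobial lists 1 of 71 and 0 of 16 genes passed in fly at 6 d, and the list totals were highest in library A. The gut list summed to 16300 CPM in fly A and 4720 in fly B against 3710 and 3590 in Sephadex, with a median of 3.16 (2.87 with bounds) over 71 genes. Only a beta-glucosidase (comp56168_c0, 3.19 ± 0.4), which splits plant glucosides, passed, and 4 were higher over the list alone. The camera call of the gut list (adjusted p = 3.5e-05, and adjusted p = 0.52 with an estimated correlation) ended without fly 6 d A (0.2). The antimicrobial list summed to 1420 and 460 CPM against 451 and 526, with a median of 1.96 (0 of 16 passed, 7 higher over the list alone, adjusted p = 0.0013, and adjusted p = 0.47 with an estimated correlation), and its call ended without Sephadex 6 d A (0.056). Diptericin comp53811_c0 had 356 CPM in fly A and 1.75 in fly B, diptericin comp48786_c0 64.8 and 0.135, and Defensin-1 (comp55661_c0) 46.5 and 0.539. Without fly 6 d A their log2 differences from Sephadex were 1.29, -0.88 and -0.34, and without fly 6 d B diptericin comp53811_c0 passed at 8.96.

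**Figure D3:**
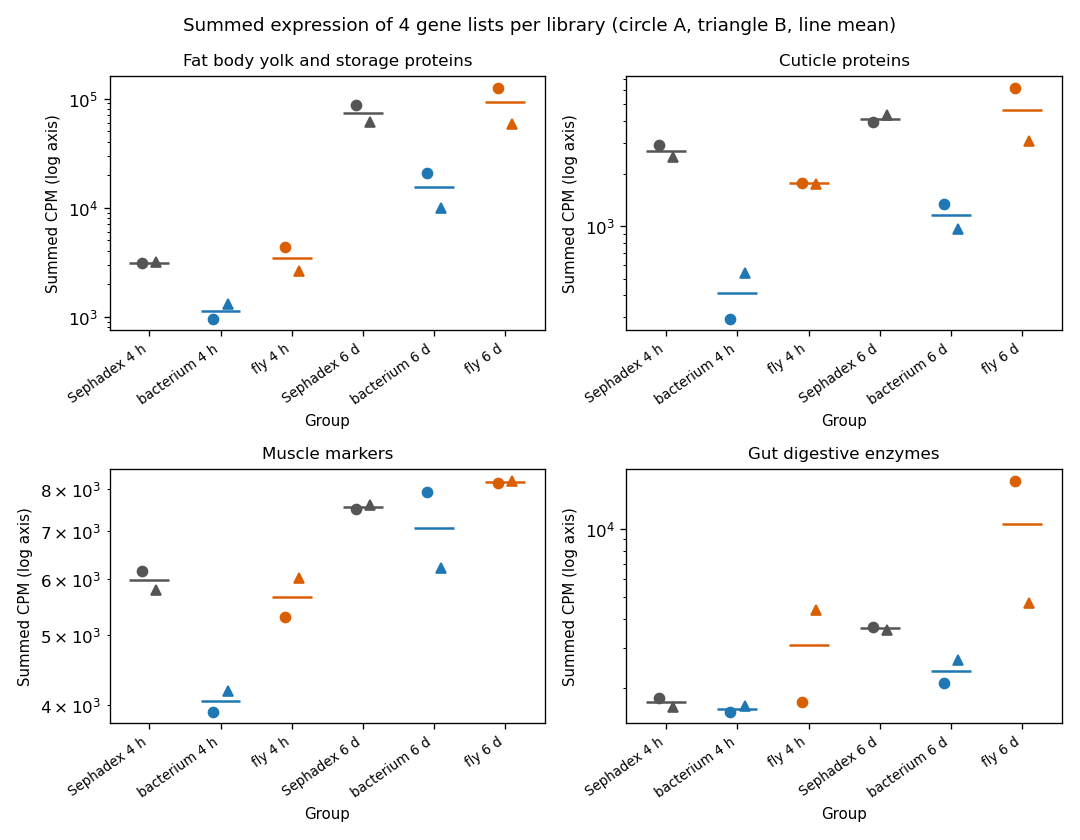
Summed CPM of 4 gene lists in each library on logarithmic axes (circle A, triangle B, line the group mean). Yolk and storage proteins summed to 956 and 1300 CPM in bacterium at 4 h and to 86800 and 60400 in Sephadex at 6 d, and the gut list was highest in fly 6 d A at 16300 CPM.

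In all 81 genes passed for the fly at 6 d (42 higher, 39 lower; 2241 at an unadjusted p under 0.05). Other camera calls were cuticle (median 0.34, adjusted p = 0.043), heat shock (median 0.11, 0.024) and cell cycle (median -0.1, 0.004), with 0 members past the test, and all 3 ended without fly 6 d A (adjusted p = 0.21, 0.07 and 0.32). The cuticle call also ended without Sephadex 6 d A (0.17) and fly 4 h A (0.059) and B (0.055), and the heat shock call without Sephadex 6 d A (0.19) and fly 6 d B (0.055). With an estimated correlation adjusted p = 0.61 for cuticle, 0.41 for heat shock and 0.46 for cell cycle, so none held. On the cell cycle list 98 of 169 members have names of mobile elements, and without them its call ended (adjusted p = 0.67). Every fly library is on the high side of the comp60900_c0 split, and with a term for it (added after seeing the data) 46 genes passed. DESeq2 called 480, the fit with no filter 257, unlisted genes at the listing limit 192 and the 4 compared libraries 7. Leaving out 1 library gave 42 calls without any 1 of the Sephadex 4 h or fly 4 h libraries, 0 and 2 without Sephadex 6 d A and B, when all 26 followed genes lost their call, and 50 and 321 without fly 6 d A and B.

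Fly against bacterium at 4 h tests directly whether these treatments differ, the wound of the fly group included. Higher in fly than in bacterium were 9 of 27 cuticle genes (16 over the list alone, median 2.08), 9 of 59 muscle markers (25, median 0.8) and 9 of 180 detoxification genes (29 higher and 1 lower, median 0.8). Against Sephadex at 4 h none of these genes passed in fly, where the list medians were -0.63, -0.08 and -0.16. SgAbd-8 (comp55933_c0) was at 28.1 ± 3.27 against 1.42 ± 0.332 CPM (4.31 ± 0.52, adjusted p = 0.011) and uricase (comp58564_c0), which degrades urate, at 19.5 ± 1.88 against 1.4 ± 0.0655. The pacifastin-related peptide (comp53092_c0) was higher by 5.59 ± 0.97, SgAbd-2 (comp52240_c0) by 4.05 ± 0.65, P450 4c3 (comp54348_c0) by 3.93 ± 0.77 and Tie-1 (comp58172_c0) by 3.73 ± 0.72. Kv channel-interacting protein 4-like (comp55749_c0, -3.94 ± 0.67), Mitotic-spindle organizing protein 1 (comp60452_c1, -1.25 ± 0.18) and aminoacylase-1-like (comp55361_c0, -0.89 ± 0.17) were lower. Of 21 yolk and storage genes 3 were higher (median 1.5) and of 154 ribosomal protein genes 2 (median 0.22). Camera adjusted p was 7.8e-11, 1e-06, 0.00063, 0.0039 and 0.0013 for cuticle, muscle, detoxification, storage and ribosomal lists, and adjusted p = 0.34, 0.46, 0.5, 0.52 and 0.77 with an estimated correlation. Without bacterium 4 h A the detoxification (0.054) and ribosomal (0.056) calls ended. The cell cycle list was called lower without names of mobile elements (3.4e-06, and adjusted p = 0.59 with an estimated correlation). In this test 311 genes passed (296 higher, 15 lower; 3238 at an unadjusted p under 0.05), 58 with the term for comp60900_c0, which separates the fly from the B library of bacterium, 905 with DESeq2, 616 with no filter and 50 with the 4 compared libraries. Leaving out 1 library gave 4 and 173 calls without bacterium 4 h A and B, 38 and 121 without fly 4 h A and B, 125 and 119 without Sephadex 4 h A and B, 148 without either Sephadex 6 d library, and 492 and 490 without fly 6 d A and B. All 9 followed genes that passed lost their call without bacterium 4 h A.

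At 6 d 153 genes were higher and 16 lower in the fly than in the bacterium libraries. Lysosomal alpha-mannosidase (comp57647_c0), which trims glycans, had 1330 ± 671 against 36.3 ± 5.87 CPM (5.19 ± 0.49, adjusted p = 0.0062). Cytochrome P450 9E1 (comp56846_c0) was higher by 4.5 ± 0.64, Fatty-acid amide hydrolase 2 (comp52714_c0) by 5.02 ± 0.87 and lysozyme C (comp54191_c0), 1 of 8 lysozymes, by 3.32 ± 0.52. An organic anion transporter (comp55591_c1) had 10.5 and 8.09 CPM in fly and no listed reads in bacterium, and seminal fluid protein HACP059 (comp23493_c0) was higher by 5.27 ± 0.89 and P450 9e2 (comp46379_c0) by 4.61 ± 0.78. D-arabinitol dehydrogenase 1 (comp56063_c0, -6.04 ± 0.86), hexamerin-like protein 1 (comp59307_c1, -2.34 ± 0.42), epithelial chloride channel (comp55238_c1, -1.2 ± 0.18), the transcriptional repressor Hairy/enhancer-of-split related 2 (comp55569_c0, -0.59 ± 0.11) and Fukutin-related protein (comp54241_c0, -0.54 ± 0.09) were lower. On the ribosomal list 0 of 154 passed (65 higher and 2 lower over the list alone, median 0.32, adjusted p = 1.2e-10), and 4 of 27 cuticle (2.3e-05), 4 of 55 melanization (0.0019), 1 of 16 antimicrobial (0.0028), 1 of 40 haemocyte (0.038, and 0.04 over the 27 members that held up to a check of names) and 3 of 71 gut genes were higher (0.018). Of 180 detoxification genes 4 were higher and 1 lower (0.024), of 21 storage genes 3 higher and 1 lower (0.029), and the cell cycle list was lower (0 of 169 passed, 0.0067, and 2.9e-05 without names of mobile elements). With an estimated correlation, adjusted p was 0.41 to 0.73 for these 9 lists, so no call held, and the pattern recognition (0.15 with camera) and Toll, IMD and JAK/STAT lists (0.11) gave no call. Without fly 6 d A the antimicrobial (0.066), haemocyte (0.14), detoxification (0.29), cell cycle (0.25) and gut (0.6, then lower) calls ended, and without bacterium 6 d B the detoxification (0.12), storage (0.48) and cell cycle (0.058) calls ended. The storage call ended with the comp60900_c0 term as well (0.11), and without Sephadex 4 h A or B (0.052 each) or Sephadex 6 d A (0.057) or B (0.055). The haemocyte call ended without bacterium 6 d A (0.13) and fly 6 d B (0.059), and the gut call without bacterium 6 d A (0.83). In all 169 genes passed (2787 at an unadjusted p under 0.05), 62 with the comp60900_c0 term, 786 with DESeq2, 418 with no filter, 295 with unlisted genes at the listing limit and 1 with the 4 compared libraries. Leaving out 1 library gave 70 calls without either Sephadex 4 h library, 86 and 85 without Sephadex 6 d A and B, 59 and 16 without bacterium 6 d A and B, 88 and 86 without fly 4 h A and B, and 61 and 980 without fly 6 d A and B. All 12 followed genes that passed lost their call without bacterium 6 d B.

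The bacterium and fly comparisons share their Sephadex libraries, so shared calls were set against simulations of groups with 1 mean per gene. At 6 d 7 genes fell with both, out of 8 for the bacterium and 39 for the fly, against 0.016 for independent calls and a mean of 0.01 and a maximum of 1 in 100 simulations. The simulated groups did not differ, so few genes could pass and a small overlap was set by the design. The figure for independent calls ignores the shared libraries. Neither value shows how many calls these libraries alone would share. The log2 fold changes correlated across genes at 0.56 (simulated 0.48) with a covariance of 0.77 (simulated 0.26). At 4 h 0 genes were shared with edgeR and 23 with DESeq2, since no gene passed for the fly (828 at an unadjusted p under 0.05), and the correlation was 0.29 (simulated 0.51) with a covariance of 0.31 (simulated 0.25). An alternative added after seeing the data gave each comparison 1 Sephadex library of its own, in the 2 possible ways. At 6 d the covariances were then 0.51 and 0.59 and the correlations 0.28 and 0.33. At 4 h the covariances were -0.03 and 0.21 and the correlations -0.02 and 0.16. In these edgeR fits no call was shared at either time. At 6 d 1 and 3 genes fell with the bacterium and 5 and 4 with the fly (1703 and 1404, and 1445 and 1639, at an unadjusted p under 0.05). At 4 h 132 and 119 fell with the bacterium and 0 with the fly (595 and 524 at an unadjusted p under 0.05).

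The change from 4 h to 6 d describes young females after each treatment. In all 3 treatments part of the storage and ribosomal protein genes rose. Of 21 yolk and storage genes 13 rose in Sephadex, 10 in bacterium and 13 in fly (17, 16 and 14 over the list alone, and 1 lower in Sephadex and in fly), with medians of 4.02 (3.59 with bounds), 2.92 and 2.39. The list summed to 3090 and 3150 CPM at 4 h and 86800 and 60400 at 6 d in Sephadex. In bacterium it went from 956 and 1300 to 20900 and 9930, and in fly from 4310 and 2620 to 126000 and 58600. The lower median in fly thus did not go with a lower total than in Sephadex. Hexamerin-like protein 2 (comp59924_c0) went from 321 ± 70.4 to 38000 ± 15700 CPM in Sephadex (6.89 ± 0.71), from 35.6 ± 2.24 to 3730 ± 1250 in bacterium (6.71 ± 0.7) and from 142 ± 61.3 to 4040 ± 3080 in fly (4.83 ± 0.64). Transferrin (comp57032_c0) rose by 3.88 ± 0.46, 2.97 ± 0.44 and 2.54 ± 0.43. Of 5 vitellogenins 3 rose in Sephadex, 2 in bacterium and 3 in fly: vitellogenin 1 (comp60767_c1) reached 274 ± 99.3, 136 ± 71.9 and 127 ± 51.6 CPM from 27.9 ± 6.29, 24.7 ± 3.45 and 28 ± 3.21. None of the 8 vitellogenin receptors passed in any of the 3, and comp59566_c0 had 1460 ± 26.4 CPM at 6 d and 1740 ± 83.5 at 4 h in Sephadex. Of 154 ribosomal protein genes 75, 61 and 74 rose (medians 0.68, 0.51 and 0.59).

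Some hormone, cuticle and immune genes also changed with time. In Sephadex juvenile hormone acid methyltransferase (comp56377_c0), a late enzyme of juvenile hormone synthesis, went from 154 ± 0.536 to 8.59 ± 8.79 CPM (-4.19 ± 0.88), and juvenile hormone binding protein (comp60465_c0), its carrier, rose by 4.66 ± 0.6. Of 27 cuticle genes 7 fell and 1 rose in Sephadex (3 higher and 11 lower over the list alone, median -1.06), while in bacterium 7 rose and 1 fell (12 and 3, median 0.92, or 0.37 with bounds) and in fly 6 rose and 5 fell (9 and 8, median 0.09). SgAbd-2 (comp58235_c0) changed by -5.77 ± 0.32 in Sephadex and -4.07 ± 0.3 in fly, and chitinase 5 (comp57880_c0), which degrades chitin, by -3.61 ± 0.56 in Sephadex. Muscle markers rose in 5, 23 and 15 of 59 genes (3 fell in fly) and detoxification genes in 7, 21 and 14 of 180 (2 fell in Sephadex, 3 in fly). PGRP-SA (comp53812_c1), a sensor of bacterial peptidoglycan, rose by 3.71 ± 0.77 in Sephadex, and of 12 peptidoglycan recognition proteins 2, 1 and 3 rose. Melanization genes rose in 7, 8 and 16 of 55 (1 fell in Sephadex), and of 7 prophenoloxidases 4, 4 and 2 rose. Antioxidant genes rose in 5, 7 and 7 of 68, among them superoxide dismutase (comp52900_c0, 2.93 ± 0.44 in Sephadex). Of 36 pattern recognition genes 3 rose and 1 fell in Sephadex, and 4 rose in bacterium and 4 in fly. Of 40 genes on the haemocyte list, 13 of which have names that do not belong there, 2, 2 and 4 rose, and of 71 gut genes 1, 6 and 6 (1 fell in Sephadex).

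The largest changes of named genes with time took in others too. In Sephadex a greglin-like protease inhibitor (comp51292_c0) went from no listed reads to 66.6 and 28.5 CPM and prophenoloxidase comp56535_c0 to 22.3 and 22.8, and seminal fluid protein HACP059 (comp23493_c0) rose by 6.69 ± 1.23, hexamerin-like protein 1 (comp59307_c0) by 6.18 ± 1 and juvenile hormone binding protein comp54544_c0 by 5.82 ± 0.83. Ejaculatory bulb-specific protein 3 (comp52381_c0) changed by -6.31 ± 0.73, I-type lysozyme (comp56111_c0) by -4.41 ± 0.61 and a takeout-like protein (comp56769_c0) by -4.22 ± 0.4. In bacterium, with no listed reads at 4 h, hexamerin-like protein 1 (comp60225_c0) had 33 and 20 CPM at 6 d, Lachesin (comp60792_c1) 26.5 and 10.5, a match named SETMAR (comp55060_c0) 9.09 and 6.48, a beta-glucosidase (comp56241_c0) 2.23 and 12.7, nephrin (comp56556_c0) 10.7 and 3.3 and the transcription factor lame duck (comp52820_c0) 7.44 and 5.91. The receptor No18 (comp48606_c0) had 30.8 and 29 CPM at 4 h and none at 6 d in bacterium, and 33.4 and 7.16 against none in fly. Aspartate aminotransferase (comp54084_c0, -3.63 ± 0.77), an amino acid transporter (comp59484_c0, -3.43 ± 0.58), a variable lymphocyte receptor A match (comp59268_c0, -2.61 ± 0.3), takeout-like (comp56769_c0, -2.32 ± 0.38) and ankyrin repeat domain protein 17 (comp56166_c0, -2.21 ± 0.41) fell in bacterium. In fly, with no listed reads at 4 h, a pol-like protein (comp60898_c0) of a mobile element had 73.4 and 20.2 CPM, atrial natriuretic peptide receptor 1-like (comp55759_c0) 22.8 and 50.8, the protease caspase-1 (comp49284_c0) 40.3 and 16.6, a SCAN domain protein (comp44369_c0) 31.7 and 7.14, takeout (comp55002_c0) 26.9 and 9.97 and prophenoloxidase comp58022_c0 17.2 and 7.14, while UDP-glucuronosyltransferase 2B20 (comp58794_c1, -5.22 ± 0.97) and SgAbd-9 (comp51230_c0, -4.91 ± 1.05) fell.

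The test of time called 586 genes in Sephadex (395 higher, 191 lower), 816 in bacterium (675, 141) and 901 in fly (699, 202). Camera adjusted p for storage was 8.4e-16, 1.9e-08 and 8.6e-09 and for ribosomal proteins 2.1e-30, 7.9e-17 and 1.8e-23. For cuticle it was 0.00092 (lower) in Sephadex and 0.029 (higher) in bacterium, the latter ending at 0.061 with the comp60900_c0 term, and for muscle 0.0017, 1.2e-10 and 1e-05. Melanization (7.9e-06, 0.0092, 2.1e-06), antioxidant (0.00058, 0.00067, 1.7e-05) and detoxification lists (0.014, 7.7e-06, 0.0013) were higher. In bacterium the gut list was higher (0.0066) and the antimicrobial list lower (0.032, 0 of 16 passed), and both calls ended without bacterium 6 d B (0.32 and 0.32). The gut call also ended without bacterium 4 h A (0.055), the antimicrobial call without Sephadex 6 d A (0.057) and B (0.055) and bacterium 4 h B (0.11), the cuticle call without bacterium 4 h A (0.26) and the melanization call without bacterium 6 d A (0.082). In Sephadex the detoxification call ended without Sephadex 4 h B (0.059). In fly the gut (6e-06), pattern recognition (0.00029) and haemocyte (0.047) lists were higher and the cell cycle list lower (0.012, 1 rose and 1 fell), the last 2 ending without fly 6 d A (0.12 and 0.25) and the cell cycle call also without names of mobile elements (0.071). The haemocyte call (0.038 with names checked) also ended without Sephadex 4 h A or B (0.052 each), fly 4 h A (0.19) and fly 6 d B (0.068). Without names of mobile elements the cell cycle list was called lower in bacterium (0.017, and adjusted p = 0.77 with an estimated correlation). With an estimated correlation, adjusted p was at least 0.34 for every list, so no call held.

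DESeq2 called 1132, 1590 and 1702 genes with time in Sephadex, bacterium and fly, and fits of the 4 compared libraries 1563, 19 and 88, so the latter 2 counts rest on the spread of all groups. With the comp60900_c0 term the bacterium count was 493. For Sephadex, leaving out 1 library gave 41 and 53 calls without Sephadex 4 h A and B, 105 and 237 without Sephadex 6 d A and B, and 921 and 911 without fly 6 d A and B. For bacterium it gave 437 and 438 without Sephadex 4 h A and B, 464 and 467 without Sephadex 6 d A and B, 54 and 291 without bacterium 4 h A and B, 139 without bacterium 6 d A, and 1241 and 1240 without fly 6 d A and B. For fly it gave 553 and 552 without Sephadex 4 h A and B, 565 and 562 without Sephadex 6 d A and B, 78 and 114 without fly 4 h A and B, and 318 and 1715 without fly 6 d A and B. Of 23 followed genes that passed in Sephadex 18 lost their call without Sephadex 4 h A, of 16 in bacterium 12 without bacterium 4 h A, and of 17 in fly 14 without fly 4 h A.

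Lists of the ovary and of other regulators gave no camera call in the 9 comparisons with all 12 libraries and every matched member. The smallest adjusted p was 0.081 for 12 genes of yolk uptake, vitelline membrane and chorion (medians of -0.22 to 0.22), 0.05 for 41 germline and oocyte genes (-0.09 to 0.07), 0.11 for 29 Toll, IMD and JAK/STAT genes, 0.071 for 133 lipid and sugar metabolism genes, 0.14 for 47 juvenile hormone genes, 0.18 for 22 ecdysone genes, 0.27 for 32 insulin and TOR genes and 0.12 for 74 nerve markers. With names checked, an alternative added after seeing the data, camera called nerve markers in bacterium against Sephadex at 6 d (0.049, and adjusted p = 0.77 with an estimated correlation) and lipid and sugar metabolism with time in fly (0.045, and 0.49). With the replicate block it called germline and oocyte genes in fly against bacterium at 4 h (0.038, lower). With an estimated correlation and no block, the smallest camera adjusted p of that list over the 9 comparisons was 0.57.

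Camera was run without each library in turn with the preset correlation only. With all 12 libraries and an estimated correlation, its adjusted p was at least 0.34 for every list. Some lists without a call gained one when 1 library was left out, higher unless noted. For bacterium at 4 h these were germline and oocyte genes without Sephadex 4 h B (adjusted p = 0.042) and fly 6 d A (0.039) and B (0.036), and nerve markers without bacterium 4 h A (0.034). For bacterium at 6 d they were muscle without bacterium 6 d A (0.015, lower) and gut without that library (0.0054) and fly 6 d A (0.018) and B (0.027). For fly at 4 h they were detoxification, lower, without Sephadex 4 h B (0.037), bacterium 4 h A (0.043) and B (0.044), and fly 6 d A (0.047) and B (0.044), yolk uptake without fly 4 h A (0.043), and ribosomal proteins (0.022) and muscle (0.035, lower) without fly 4 h B. For fly at 6 d they were pattern recognition (0.034) and antioxidant (0.0032) without fly 6 d B, and yolk uptake (0.0054), ribosomal proteins (0.0056, lower) and nerve (0.0033) without fly 6 d A. Storage was called lower for fly at 6 d without bacterium 4 h A (0.014) and B (0.013) and with the comp60900_c0 term (0.039). In fly against bacterium at 4 h they were all lower, namely heat shock without bacterium 4 h A (0.037), germline without fly 4 h B (0.0061) and fly 6 d A (0.033) and B (0.032), and nerve without fly 4 h B (0.035). At 6 d they were pattern recognition (0.036), antioxidant (0.0044) and nerve (0.027, lower) without fly 6 d B, muscle without bacterium 6 d A (0.00083), and Toll, IMD and JAK/STAT without bacterium 6 d A (0.043) and fly 6 d B (0.049). With time in Sephadex they were pattern recognition without Sephadex 6 d A (0.036) and bacterium 6 d A (0.042) and B (0.041), antimicrobial without Sephadex 6 d B (0.02, lower) and yolk uptake without Sephadex 4 h A (0.017, lower). With time in fly they were antimicrobial (0.01) and nerve (0.03, lower) without fly 6 d B and lipid and sugar metabolism without fly 4 h B (0.032).

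Few genes of a group had no listed reads in the other treatments: 6 genes had 10 or more reads in both fly 6 d libraries and none listed in the 8 Sephadex and bacterium libraries, and 0 did for fly at 4 h. The same count was 2 and 6 for Sephadex at 4 h and 6 d, with comp433170_c0 in both, and 5 and 0 for bacterium. At 5 or more reads it was 15 for fly at 6 d and 1 at 4 h, a bound added after seeing the data.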

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

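Tests chosen only after the result was seen were those of scaling by the ratio of lists to other genes, of one common loss of cuticle-bearing tissue, muscle or fat body, of gut tissue in the dissection, of reads in libraries without larvae, and the camera fits without each library in turn, although the bounds for those without bacterium 6 d B and without fly 6 d A were written before their results were seen.

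Effects that differed between the times were tested directly. The bacterium effect differed between 4 h and 6 d for 16 genes (14 higher, 2 lower; 1642 at an unadjusted p under 0.05). The 5 named ones, picked after their values were seen, all had the lower value at 4 h: obstructor-A (comp50365_c0) changed by -3.6 at 4 h and -0.27 at 6 d (difference 3.33 ± 0.22 SE, adjusted p = 0.0019), an aquaporin (comp51869_c0) by -3.57 and 0.35, protein DSCD75 (comp59917_c0) by -1.52 and 0.15, and endocuticle proteins SgAbd-2 (comp58235_c0) by -3.59 and 0.16 and SgAbd-8 (comp55933_c0) by -5.76 and -0.49. The count was 245 with DESeq2, 113 with no filter, 9 with the replicate block and 9 with the term for comp60900_c0. It was 8 and 6 without Sephadex 4 h A and B, 9 and 3 without Sephadex 6 d A and B, 6 and 40 without bacterium 4 h A and B, 25 without bacterium 6 d B, and 8 without either fly 4 h library.

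The fly effect differed between the times for 23 genes (18 higher, 5 lower; 1355 at an unadjusted p under 0.05). Of the 9 named ones, also picked after their values were seen, the prophenoloxidase comp50812_c0 stood at 1.37 at 4 h and -4.46 at 6 d (difference -5.83 ± 0.62 SE, adjusted p = 0.023), the LPS-induced TNF-alpha factor homolog (comp51431_c0) at -0.42 and 3.35, an aquaporin (comp50626_c0) at -0.85 and 2.13 and nitric oxide synthase (comp60618_c0) at -0.82 and 1.88. The others were Icarapin-like, major royal jelly protein 4, FAM151B, takeout and a tubulointerstitial nephritis antigen-like protein, with differences of 2.17, 2.45, 1.6, 1.2 and 1.38. The Sephadex value of prophenoloxidase comp50812_c0 was itself higher at 6 d, at 24.4 ± 1.65 CPM, than at 4 h. The count was 213 with DESeq2, 72 with no filter, 14 with the replicate block and 11 with the term for comp60900_c0. It was 1 and 0 without Sephadex 4 h A and B, 0 without either Sephadex 6 d or either fly 4 h library, and 4 and 85 without fly 6 d A and B.

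A component of 267 bases (comp243071_c0) whose best match is the mitochondrial 16S ribosomal RNA of a flesh fly had 24 reads in fly 4 h A, 8 in fly 4 h B and 5 in fly 6 d B. It was not listed in fly 6 d A or in the 8 Sephadex and bacterium libraries, where unlisted means under 0.3 RPKM, or at most 1.04 reads for this length.

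The first pattern is the lower cuticle, muscle and detoxification transcripts in the bacterium libraries at 4 h. Its camera calls were lost with an estimated correlation (adjusted p = 0.34, 0.46 and 0.46). With RLE size factors 90.8% of calls were lower, but these factors moved the median of all genes only from -0.03 to -0.023 and so test little. The tables argue against scaling between the libraries by another value, the median log2 ratio of a list less that of all other genes, which no scaling factor changes. Over the 4 pairs of a bacterium and a Sephadex library it was -2.47 for cuticle (-3.02 to -1.82, and at most 0.41 either way between replicates), -0.88 for muscle (-1.01 to -0.61, and 0.08) and -0.85 for detoxification (-1.23 to -0.59, and 0.32). One common loss of a tissue would lower its own genes alike. Among members at 10 CPM or more in Sephadex the SD of log2 fold changes was 1.32 for 15 cuticle genes against a median SE of 0.43, and 1.38 for 40 muscle genes against 0.21. Genes that other tissues of the sample express too would fall less, so these spreads exclude nothing, and a smaller share of cuticle-bearing tissue or muscle in the dissection and a response to the bacterium cannot be told apart for these 2 lists. A response to the bacterium, which the design names, may account for the pattern and stays untested. The contrast with Sephadex alone does not separate that response from an effect of the beads, as no untreated group is in the series. In fly against bacterium at 4 h the same lists were higher in fly.

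The second pattern is the higher gut digestive enzyme transcripts in the fly libraries at 6 d, with 1 of 71 genes past the test and adjusted p = 0.52 with an estimated correlation. For the tested gut genes with a log2 fold change of 2 or more, the reads argue against the fly larvae as their only source. Of these genes, 0% (0 of 38) had fewer than 10 reads in each library without larvae (exact 95% bounds 0 to 9.3%). The filter had kept 71 of 117 gut genes, and it drops genes read in 1 library alone. Larval genes read only in fly 6 d A were thus outside this test, which cannot exclude larval RNA in that library. The odds ratio of a dipteran best hit, 1.13 (0.22 to 3.66), decides nothing. The pattern is largely one library, since camera p was 0.081 without fly 6 d A and 4.4e-06 with it, and the median log2 fold change of the 71 genes was 0 without it (26 higher, 26 lower) and 3.16 with it. Gut tissue in the dissection of fly 6 d A may contribute and stays open: 78.2% of 55 gut genes were higher in A than in B (65% to 88.2%), against 51.9% of 12296 other genes. This excess is not particular to gut, since the share was 78.3% for pattern recognition, 74.6% for antioxidant and 73.4% for ribosomal genes, with median log2 ratios of 0.78, 0.28 and 0.25 against 2.88 for gut. In the bacterium libraries at 6 d 49 of 71 gut genes had a higher value than in Sephadex (median 0.68, or 0.53 with bounds, 0 past the test) and 58 a higher value than at 4 h (2.48, or 2.17, with 6 past it). A response to the larvae that was stronger in 1 library cannot be told apart from it, because the other library is the only one to compare.

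The third pattern is the lower storage and ribosomal protein transcripts in the bacterium libraries at 6 d. It rests on the preset correlation, since 0 of 21 storage and 0 of 154 ribosomal genes passed and adjusted p = 0.37 and 0.49 with an estimated correlation. With the preset correlation no one library makes it: without bacterium 6 d B camera p was 2.2e-05 for the storage list and 6.7e-12 for the ribosomal list, and without each of the 12 libraries in turn at most 2.2e-05 and 3.2e-08, all lower. A slower change with time from a level start would leave the genes that fell with time in fly higher, but their median log2 fold change was -0.14 over 202 genes, and -0.13 and -0.28 with bacterium A or B alone, while the 699 that rose had -0.48. The start was not level, since 575 of 626 genes called at 4 h were already lower in bacterium. This test therefore cannot decide, and a slower change stays open. For one common loss of fat body the SD over 17 storage genes was 1.13 against a median SE of 0.63, which excludes nothing for the same reason as above, while the lipid and sugar metabolism list had a median of 0. A smaller share of fat body in the dissection and a lasting effect of the bacterium on fat body output may each contribute and cannot be told apart.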

How the results depend on the processing

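Counts are in the order bacterium 4 h, bacterium 6 d, fly 4 h, fly 6 d, fly against bacterium 4 h and 6 d, time in Sephadex, bacterium and fly, change of the bacterium effect and of the fly effect. The term for comp60900_c0, the listing limit, the names check with both correlations, the bound of 5 reads, 1 Sephadex library per comparison and the camera fits without 1 library were chosen after seeing the data; the other alternatives were planned. RLE size factors, the stricter filter and an absolute log2 fold change of at least 1 kept all 11 counts within 1.5 times. DESeq2 gave 1323, 415, 31, 480, 905, 786, 1132, 1590, 1702, 245 and 213. The replicate block moved the last 2, to 9 and 14. With no filter 106, 2, 257, 616, 418, 113 and 72 passed for bacterium 6 d, fly 4 h, fly 6 d, both fly against bacterium tests and both changes. Only the compared libraries gave 1252, 0, 2, 7, 50 and 1 for the first 6 and 1563, 19 and 88 with time. The comp60900_c0 term gave 46 for fly 6 d, 58 and 62 for fly against bacterium, 493 with time in bacterium, and 9 and 11 for the changes. The listing limit gave 46, 192 and 295 for bacterium 6 d, fly 6 d and fly against bacterium at 6 d. Leaving out 1 library gave 39 to 903, 1 to 76, 0 to 1, 0 to 321, 4 to 492, 16 to 980, 41 to 921, 54 to 1241, 78 to 1715, 3 to 40 and 0 to 85. Of 58 list calls 0 held with an estimated correlation, which has little power here. The other alternatives gave 52 to 67 list calls. These totals count new calls too and do not show how many of the 58 held. Shared calls with DESeq2 were 23 at 4 h and 110 at 6 d, and with 1 Sephadex library per comparison 0 at both. Genes in the fly libraries alone were 1 at 4 h and 15 at 6 d at 5 reads. Of 148 followed gene results past the test none turned, 12 passed in all alternatives and 136 lost their call in at least 1. Of 21 not past it 16 passed in at least 1 and 3 turned: thaumatin-like comp50965_c0 was 5.63 without Sephadex 4 h A and -0.14 without fly 4 h B, and diptericin comp48786_c0 -0.88 and Defensin-1 -0.34 without fly 6 d A. Fewer samples, fewer residual degrees of freedom or more genes tested go with the alternatives by construction. The fly 6 d pair differed most between replicates (SD of log2 ratios 0.73) and adds to the spread that all groups share. Without either of its libraries the counts rose in the comparisons that do not use this group, except fly at 4 h. Those counts therefore depend on the spread of this pair. Otherwise the cause was not tested. Depth limits genes near 0.3 RPKM, where a value under the limit is not listed.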

Other observations

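The cell cycle list holds 98 mobile-element names, and a check of its members by name, chosen after the data were seen, leaves 71 genes. In bacterium at 4 h 61 of these 71 were higher than in Sephadex, with a median log2 fold change of 0.25 (1 gene past the test, camera adjusted p = 8.6e-09, and adjusted p = 0.51 with an estimated correlation). DNA polymerase delta small subunit (comp42436_c0), a part of an enzyme that copies DNA, rose by 0.78 ± 0.15 SE. Others of the smallest p did not pass: Origin recognition complex subunit 6 (comp49029_c0) stood at 0.52 ± 0.14 (adjusted p = 0.081), cell division control protein 6 (comp58222_c0) at 0.47 ± 0.13 (0.087), the replication licensing factor MCM4 (comp57476_c0) at 0.39 ± 0.11 (0.098) and the mitotic cyclin-B3 (comp52501_c0) at 0.39 ± 0.11 (0.098). At 4 h the germline and oocyte list summed to 3730 and 3790 CPM in bacterium against 3400 and 3500 in Sephadex. The yolk uptake list summed to 8230 and 8890 against 7220 and 8680. The samples mix fat body and ovary, so a larger share of ovary and a change within cells cannot be told apart. In bacterium at 6 d 58 of the 71 were higher (median 0.13, camera adjusted p = 7.4e-05, and adjusted p = 0.61 with an estimated correlation). In fly 54 were higher at 4 h (median 0.05, camera adjusted p = 0.01, and adjusted p = 0.75 with an estimated correlation) and 29 at 6 d (median -0.02, camera adjusted p = 0.67). In fly against bacterium 11 were higher at 4 h (median -0.18, camera adjusted p = 3.4e-06) and 14 at 6 d (median -0.15, 2.9e-05), with adjusted p = 0.59 and 0.59 with an estimated correlation. From 4 h to 6 d 31 were higher in Sephadex, 22 in bacterium and 17 in fly (medians -0.04, -0.1 and -0.09, camera adjusted p = 0.98, 0.017 and 0.071), and for bacterium adjusted p = 0.77 with an estimated correlation.

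In fly 6 d against 4 h, 4 of 36 pattern recognition genes rose (camera adjusted p = 0.00029, and adjusted p = 0.46 with an estimated correlation). In bacterium 4 rose as well (0.18 with camera), and in Sephadex 3 rose and 1 fell (0.061). Among genes picked after their values were seen, GNBP3 (comp53744_c0) rose by 2.51 ± 0.31, to 242 and 166 from 40.7 and 30.7 CPM, Peptidoglycan-recognition protein LE (comp59179_c0) by 1.75 ± 0.36, C-type lectin 10 (comp53306_c0) by 3.11 ± 0.55 and integrin alpha-PS2 (comp58452_c0), a cell adhesion receptor, by 2.67 ± 0.28. A juvenile hormone esterase (comp53507_c0) had 22.8 and 12.6 CPM at 4 h and no listed reads at 6 d, and juvenile hormone acid methyltransferase (comp56377_c0) 62.2 and 260 CPM at 4 h and 0 and 0.404 at 6 d.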
